A study of Mus musculus with 13 samples.

How the data were processed

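Whole injured hamstring muscle was taken from 13 mice at day 4, with 1 library per mouse from 4 saline and 9 dexamethasone mice. Per the labels' protocols, RNA was enriched for polyadenylated transcripts and made into stranded libraries. Another saline mouse was excluded by the submitters because bone had formed in its muscle, and its 1 column of values was not used here. Groups came from the labels.

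Per the submitters' processing notes, reads were counted with featureCounts 2.0.1 on the mouse build mm10 and handled with limma 3.50.1. The aligner and any filter on low genes are not given in the sources used here. The authors deposited log2 CPM values per mouse, with log2 fold changes and p-values of their own comparison. Tables normalised with and without that excluded mouse were both deposited. The table without that mouse, with 14911 genes, was the main one, and the other held 14970 genes. The deposited log2 values were exactly log2 of reads plus 0.5 over an effective library size, scaled to CPM, so whole reads were recovered in 100% of values within 0.01 of a whole number. The effective size was 0.952 ± 0.056 times the summed reads in saline (SD, n = 4) and 1.03 ± 0.036 times in dexamethasone (SD, n = 9; exact permutation p of 0.0112). The 10 largest genes took 17.2% and 14.8% of reads (exact permutation p of 0.0252). In the authors' deposited table, 7010 genes had an adjusted p under 0.05, 6944 of them also called here and in the same direction.

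Expression was compared with a linear model in limma 3.58.1 (R 4.3.3), moderated with an intensity trend, two-sided, with Benjamini-Hochberg adjustment at 0.05. A fold change is a difference of mean log2 CPM, so folds of low genes depend on the 0.5 offset. Gene lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry beside it, adjusted over the 30 lists of at least 5 measured members. The mean of each list in each library was compared by an exact permutation test over the 715 splits into 4 and 9, two-sided, whose smallest p is 0.0028. A single list at that p cannot pass adjustment over 30 lists unless other lists differ too. With 1 saline library left out the smallest p is 0.00909, and with 1 dexamethasone library left out it is 0.00404. Such a call can thus end with little change in the difference.

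Coordinates were matched through Entrez identifiers to a RefSeq table of the same build, for 14909 genes. Named genes were the 10 largest rises and 10 largest falls among called genes with a mean log2 CPM of at least 1, without predicted genes, Riken clones and pseudogenes. A fixed set of hormone, muscle, bone and immune genes was added, with up to 4 members per list of smallest adjusted p and mean log2 CPM of at least 0. Some genes that the rule picked are not reported here. Genes outside that rule are said to be so where named. The lists, tests, named gene rule and alternatives were fixed before the data were examined. Some lists share genes, such as Spp1, Alpl, Tnc and Egr1.

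The steps were tested on simulated data. For the comparison of dexamethasone with saline over 14911 genes, 94 of 100 genes changed by 1 on the log2 scale were recovered, and 64 of 100 changed by 0.5. Of 168 calls, 10 (5.95%) were false. A cell cycle list moved alone was called by camera, and 0 lists by the library means. The latter tells nothing of the library means, whose adjustment a single list cannot pass unless other lists differ too. Simulated noise was independent between genes, whereas the cell cycle list had an estimated correlation of 0.817 in the data. Far fewer genes were changed than were called in the data. The simulation therefore does not test camera at the preset correlation, nor the share of false calls in the data. Among 42 pairs of libraries of the same group, the chi-square per gene of recovered reads was at least 7.21, so each library counted as 1 sample.

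Alternatives were the other deposited table, log2 of CPM plus 1, a filter on low genes, median centring, quantile normalisation, moderation without a trend or with robust priors, library weights, voom on recovered reads, exact rank sum tests, the mouse number as a block, the mature fibre list mean as a covariate, and each library left out. Leaving out saline library 3 and dexamethasone library 4 together, voom for lists and single genes, and the 8 numbered libraries without the block were added after seeing the data. A direction was called reversed only where the value was past the threshold in either fit. The figures were drawn with matplotlib 3.10.9.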

Results

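The series measured messenger RNA in whole hamstring muscle of female C57BL/6 mice 4 days after an injection of cardiotoxin, a snake venom toxin that destroys muscle fibres, at 0.32 mg/kg. Mice then received daily intraperitoneal saline or dexamethasone, a synthetic glucocorticoid, at 10 mg/kg. Libraries from 4 saline mice and 9 dexamethasone mice were compared, each library coming from a separate mouse. The deposited values gave back 25531487 to 34942266 whole reads per library over 14911 genes. Saline libraries held 25531487 to 32537345 reads and dexamethasone libraries 28021111 to 34942266, a difference of means with an exact permutation p of 0.49. The submitters state that bone had formed in injured muscle of every dexamethasone mouse, at 2.40 ± 5.42 mm3. They excluded a saline mouse because bone had formed in its muscle, so the saline libraries were selected on bone. Differences tied to the drug and to bone formation therefore cannot be told apart in this comparison. Bone volumes of single mice were not analysed here.

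The comparison asked which transcripts of injured muscle differed under dexamethasone. Lcn2, which encodes an iron-carrier binding protein of acute inflammation, rose from 2.36 ± 1.82 to 7.33 ± 0.46 log2 CPM (depth-scaled read counts; SD, n = 4 and 9). Saa3, an acute phase serum amyloid, rose 16.4-fold and Hp, which encodes haptoglobin, 7.12-fold. Actc1, the cardiac actin of developing and regenerating muscle, was 5.52-fold lower, and Atp1b4, a muscle protein of the nuclear envelope, was 6.89-fold lower. In all, 7173 of 14911 genes passed an adjusted p of 0.05 (limma with Benjamini-Hochberg adjustment), 3760 higher and 3413 lower. At least 2-fold changes numbered 774, of which 373 were higher and 401 lower. The excess of falls rested on low genes and single libraries: 231 were higher and 145 lower with genes of mean log2 CPM of at least 1, 178 and 140 with log2 of CPM plus 1, and 433 and 366 without saline library 5. In 3845 genes (25.8%) the groups did not overlap, where chance gives 0.28%. The first principal component held 44.2% of the variance, with saline libraries at -47.7 to -39.4 and dexamethasone libraries at 12.9 to 33.4. The count fell to 3381 when the mean of a mature myofibre list was added as a covariate. That mean was itself lower in all 9 dexamethasone libraries than in any saline library, so the covariate overlapped with group.

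Other large rises came from secreted protease inhibitors, a chemokine, a matrix enzyme and myeloid proteins. Serpina3n (Entrez 20716, mm10 chromosome 12, 104406646 to 104414334) rose by 3.51 ± 0.24 on the log2 scale (SE). Its neighbour Serpina3m had 1 to 3 reads in each saline library and 131 to 753 in dexamethasone libraries, a log2 fold change of 6.64 that depends on the offset. Both belong to a family of similar copies, so reads between them are uncertain. Ccl2, which attracts monocytes, rose 9.92-fold. Has1, a hyaluronan synthase, rose 8.66-fold. Chil3, a macrophage chitinase-like protein with close copies in the genome, rose 11.9-fold and Clec4e, a myeloid receptor, 7.41-fold. Without saline library 3 the log2 fold change of Chil3 was 4.27 instead of 3.58 and that of Lcn2 was 5.87 instead of 4.97. Each of these 9 genes, with Lcn2, Saa3 and Hp among them, was higher in all 9 dexamethasone libraries than in any saline library.

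Among the falls, Glycam1, a mucin of lymph node vessels, went from 4.63 ± 0.30 to 1.88 ± 0.67 log2 CPM (SD, n = 4 and 9). Cd4, of helper T cells, was 5.24-fold lower. Cd79a and Cd79b, subunits of the B cell receptor, were 4.83- and 5.03-fold lower. Ighd, the constant region of immunoglobulin D, was 4.83-fold lower and Spib, a B cell and plasmacytoid dendritic cell transcription factor, 4.36-fold. Retnla, a product of alternatively activated macrophages, was 4.59-fold lower. Arrdc2, a hormone-induced arrestin-like gene, was 4.56-fold lower, but dexamethasone library 4 lay within the saline range.

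**Figure D1:**
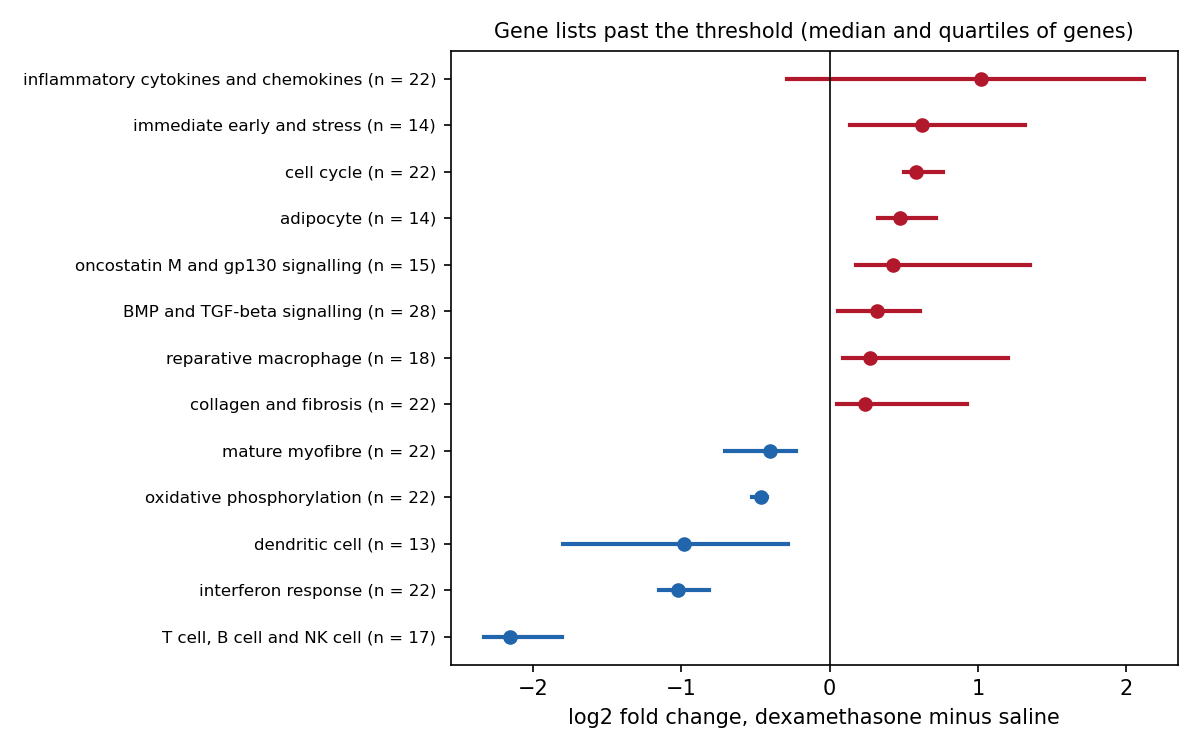
The 13 gene lists past the threshold are shown by the log2 fold change of their measured genes, dexamethasone minus saline. Points are medians over genes, lines run between the quartiles and n is the number of measured genes. The list of T, B and NK cells has the lowest median, -2.15.

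Of 31 gene lists fixed before the data were examined, 30 had at least 5 measured members and 13 passed camera with a preset correlation of 0.01, 8 higher and 5 lower. With an estimated correlation 0 of 30 passed, 4 having an unadjusted p under 0.05, and 17 passed fry. By the mean of each library, 16 lists differed in an exact permutation test, 12 of them among the 13. Of all 14911 genes 48.1% were called, 3760 higher and 3413 lower. A list with about that share of members called in both directions does not stand out from other genes.

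Lymphocyte markers fell throughout. All 17 measured T, B and NK cell genes fell, and 17 fell adjusted over the list alone (median log2 fold change -2.15). Lck, a T cell kinase, was 4.55-fold lower. The list mean went from 1.38 ± 0.25 to -0.67 ± 0.48 log2 CPM (SD, n = 4 and 9) and all 9 dexamethasone libraries lay below every saline library. With genes of mean log2 CPM of at least 1 the list kept under 5 members and was not tested. The camera adjusted p was 3.65e-08, with adjusted p = 0.296 with an estimated correlation. Of 13 dendritic cell genes, 9 fell and 1 rose, both counts unchanged when adjusted over the list alone. The class II antigen presentation genes H2-Ab1, H2-Eb1 and H2-Aa were 3.48-, 3.88- and 3.83-fold lower, and Clec9a, of cross-presenting dendritic cells, was 2.81-fold lower. By camera the list had an adjusted p of 0.000455, and adjusted p = 0.296 with an estimated correlation.

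Interferon response genes fell in the same libraries. All 22 measured members fell, 22 also adjusted over the list alone, with a median log2 fold change of -1.02. Ifit3 and Ifit2, interferon-induced RNA-binding proteins, were 3.10- and 2.21-fold lower, and the guanylate-binding proteins Gbp3 and Gbp2 were 2.32- and 1.78-fold lower. Camera gave an adjusted p of 2.12e-10, and adjusted p = 0.519 with an estimated correlation.

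Cytokine genes moved both ways, with more rises. Of 22 measured, 13 rose and 4 fell, or 13 and 5 adjusted over the list alone. Ccl7, a monocyte chemokine, rose 6.07-fold, Ptgs2, the inducible cyclooxygenase, 6.75-fold and Csf1, the macrophage growth factor, 2.10-fold. Ccl5, a T cell chemokine, fell by 1.97 and Cxcl9, an interferon-induced chemokine, fell by 1.10 on the log2 scale; both were named after their values were seen. The camera adjusted p was 0.022, with adjusted p = 0.665 with an estimated correlation. The call ended with genes of mean log2 CPM of at least 1 (adjusted p = 0.187), with the fibre covariate (adjusted p = 0.0654) and with voom on recovered reads (adjusted p = 0.081).

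Genes of oncostatin M, a macrophage cytokine, and of its shared receptor gp130 rose. Of 15 measured, 10 rose and 1 fell, and the same numbers held adjusted over the list alone. Osm itself rose 2.69-fold (adjusted p 0.000485, limma). Socs3, the feedback inhibitor of this pathway, rose 4.73-fold, Lif, a related cytokine, 6.37-fold and Bcl3 2.42-fold. Il6st, which encodes gp130, rose 1.34-fold. By camera the list had an adjusted p of 0.000308, and adjusted p = 0.147 with an estimated correlation.

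Macrophage genes did not move together. Of 20 general markers 5 rose and 4 fell, or 5 and 3 adjusted over the list alone (camera adjusted p 0.849). The balance hung on single libraries, with 3 higher and 6 lower without saline library 1, and 7 higher and 3 lower without saline library 5. Itgam and Cd68 rose 1.72- and 1.39-fold, while Cd74, the class II invariant chain, was 3.48-fold lower and Aif1 1.70-fold lower. Adgre1, the F4/80 antigen, had a log2 fold change of 0.18 ± 0.08 (SE; adjusted p 0.0792, limma), and 0.28 without saline library 5 (adjusted p 0.0057, limma). Of 18 reparative macrophage genes 11 rose and 1 fell, or 11 and 2 adjusted over the list alone. Mrc1, the mannose receptor, rose 2.50-fold and Anxa1, a hormone-induced annexin, 1.80-fold, while Retnla of the same list fell. Camera gave an adjusted p of 0.0154, and adjusted p = 0.60 with an estimated correlation. That call ended with the fibre covariate (adjusted p = 0.144).

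Neutrophil genes were set by saline library 3. Of 15 measured, 2 rose and 2 fell, or 1 and 1 adjusted over the list alone (camera adjusted p 0.849). S100a8, a neutrophil calcium-binding protein, was at 0.76 ± 3.53 and 1.70 ± 0.99 log2 CPM (SD, n = 4 and 9; adjusted p 0.47, limma). Mmp8, a neutrophil collagenase, rose 3.30-fold, a call lost when any of 9 libraries was left out, with log2 fold changes from 0.94 (without saline library 2) to 2.79 (without saline library 3; adjusted p 8.27e-05, limma). Csf3r was 1.27-fold lower, a call lost without saline library 3 (adjusted p 0.0518, limma) or 5 (adjusted p 0.0618, limma). Without saline library 3 the list passed, with a median of 1.35 and a camera adjusted p of 0.0439, and S100a8 had a log2 fold change of 2.65 (adjusted p 0.00163, limma), against 0.94 with it, 0.18 without saline library 2 and 0.14 without saline library 5. Ly6g was not analysed here.

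Established glucocorticoid receptor targets split. Of 22 measured, 8 rose and 4 fell, counts unchanged when adjusted over the list alone (median 0.031, camera adjusted p 0.357). By library mean the list went from 5.49 ± 0.09 to 5.86 ± 0.38 log2 CPM (SD, n = 4 and 9; exact permutation, adjusted p 0.00699). That difference of 0.36 was 0.24 without dexamethasone library 4 (exact permutation, adjusted p 0.0101), and the call was lost with members scaled to unit SD (exact permutation, adjusted p 0.407). Lcn2, a member of this list, rose by 4.97 on the log2 scale, and by 4.87 without dexamethasone library 4. It carried much of both differences in the mean, whereas the median over members was 0.031. Angptl4, a lipase inhibitor, rose 3.42-fold, Mt2, a metallothionein, 4.00-fold and Errfi1 1.96-fold. Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, was 1.67-fold lower. Fkbp5, a receptor cochaperone, had a log2 fold change of 0.46 ± 0.26 (SE; adjusted p 0.158, limma) and Per1, a clock gene, 0.011 ± 0.17 (adjusted p 0.964, limma). Per1 passed as lower on the 8 libraries numbered in both groups, with the number as a block.

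Dexamethasone library 4 decided several of these values. It was the highest dexamethasone library for 20 of the 22 targets. Fkbp5 stood at 7.92 log2 CPM there, against 6.12 ± 0.05 in the other 8 (SD). Without that library 10 targets rose and 7 fell, and Fkbp5 passed at a log2 fold change of 0.26 ± 0.05 (SE; adjusted p 0.00123, limma). Arrdc2 then fell by 2.51 and Tsc22d3 fell by 0.84 on the log2 scale. Nr3c1, the receptor itself, was 1.25-fold lower (adjusted p 0.00336, limma). In the list of receptor and hormone metabolism 4 of 9 rose and 3 fell, likewise adjusted over the list alone (camera adjusted p 0.788). Its library mean went from 6.10 ± 0.05 to 6.23 ± 0.08 log2 CPM (SD, n = 4 and 9; exact permutation, adjusted p 0.024), and fry gave an adjusted p of 0.0224. The library mean call ended without saline library 2 (adjusted p 0.0545), 3 (adjusted p 0.0606) or 5 (adjusted p 0.0779). The difference in these fits was 0.14, 0.12 and 0.11, against 0.13 over all 13 libraries. The call also ended with median centring (adjusted p 0.0886) or members scaled to unit SD (adjusted p 0.147). It ended as well with saline library 3 and dexamethasone library 4 left out together (adjusted p 0.0766). Hsp90aa1, H6pd and Por rose 1.49-, 1.29- and 1.35-fold.

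**Figure D2:**
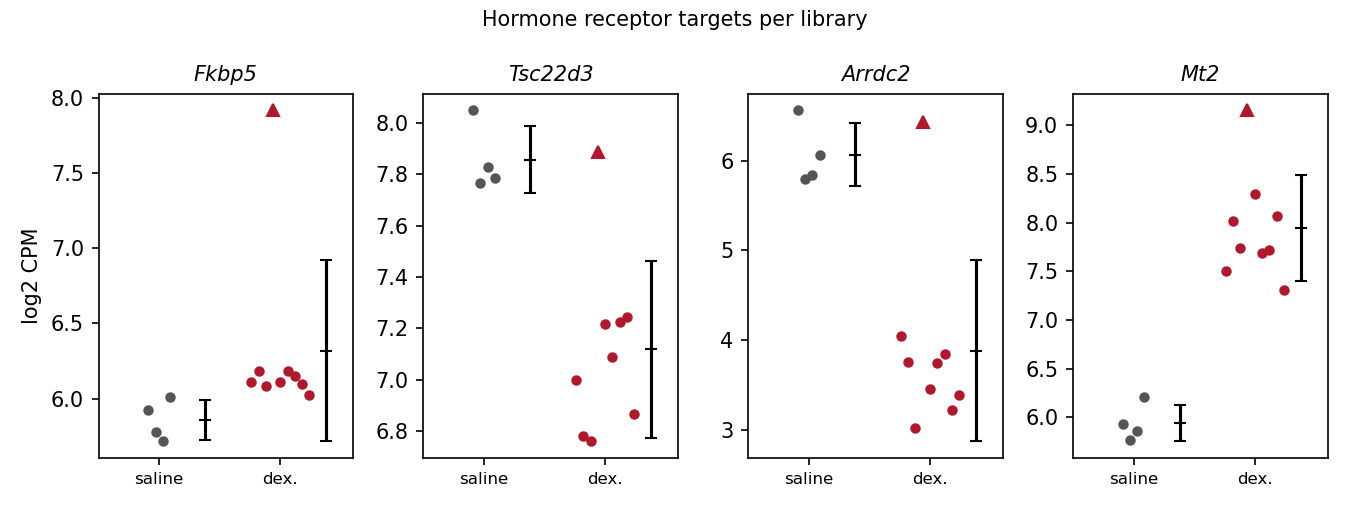
Log2 CPM of 4 glucocorticoid receptor targets in each library, 4 saline in grey and 9 dexamethasone in red, with library 4 as a triangle. Bars are mean ± SD. Fkbp5 is at 7.92 in library 4 and at most 6.18 in the other 8, and each panel has its own axis.

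Genes of mature fibres fell. Of 22 measured, 10 fell and 0 rose, the same adjusted over the list alone, with a median log2 fold change of -0.40. Casq1, a calcium store protein, was 1.95-fold lower, Eno3, muscle enolase, 1.90-fold, Myl1, a myosin light chain, 1.78-fold and Tnnt1, slow troponin T, 1.61-fold. The list mean went from 12.41 ± 0.23 to 11.95 ± 0.17 log2 CPM (SD, n = 4 and 9). The camera adjusted p was 7.17e-05, with adjusted p = 0.665 with an estimated correlation. Under quantile normalisation the call was lost (median -0.090, adjusted p = 0.261).

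Nuclear genes of oxidative phosphorylation fell with them. Of 22 measured, 21 fell and 0 rose, the same adjusted over the list alone, with a median of -0.46. Sdhb, Atp5o, Cox5b and Cox4i1, of respiratory complexes, were 1.55-, 1.54-, 1.45- and 1.44-fold lower. By camera the list had an adjusted p of 2.12e-10, and adjusted p = 0.569 with an estimated correlation. The mature fibre list fell in the same libraries. Mitochondrially encoded genes were not analysed here.

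Regeneration genes were mixed. Of 16 genes of myocyte differentiation and fusion, 4 rose and 7 fell, the same adjusted over the list alone (camera adjusted p 0.151). Myh8, perinatal myosin, went from 10.5 ± 0.08 to 9.48 ± 0.27 log2 CPM (SD, n = 4 and 9). Itgb1bp2 was 1.97-fold lower, Myom3 1.65-fold and Myh3, embryonic myosin, 1.29-fold lower. Myog, which drives differentiation, had a log2 fold change of 0.30 ± 0.15 (SE; adjusted p 0.11, limma), and 0.49 without saline library 5 (adjusted p 0.00641, limma). The Myh3 call ended without saline library 3 (adjusted p 0.0644, limma) or 5 (adjusted p 0.059, limma), and the list passed without saline library 2, with 2 higher and 6 lower (camera adjusted p 0.0477). Without saline library 5 the list had 6 higher and 6 lower, with a median of -0.019 against -0.16 (camera adjusted p 0.48). It also passed with the fibre covariate (median -0.37, camera adjusted p 0.00324) and by fry (adjusted p 0.0217), and had an adjusted p of 0.0559 by library means (exact permutation). Of 13 satellite cell and myoblast genes, 5 rose and 2 fell, or 6 and 2 adjusted over the list alone (camera adjusted p 0.588). Myod1, the myoblast determination factor, rose 1.41-fold and Megf10 2.12-fold, while Chodl was 2.25-fold lower. The Myod1 call ended without saline library 1 (adjusted p 0.0536, limma) or 2 (adjusted p 0.0553, limma). Pax7, the satellite cell factor, had a log2 fold change of -0.13 ± 0.13 (SE; adjusted p 0.445, limma). Of 18 muscle atrophy genes 9 rose and 3 fell, likewise adjusted over the list alone (camera adjusted p 0.151). Ctsl, a lysosomal protease, rose 1.89-fold and Eif4ebp1, a translation repressor, 1.61-fold, and Foxo1 was 1.40-fold lower. The atrophy list passed without saline library 1 (camera adjusted p 0.0353), with the fibre covariate (median 0.34, camera adjusted p 0.00676) and by fry (adjusted p 0.0416). By library means it had an adjusted p of 0.0751 in the exact permutation test.

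Cell cycle genes rose. Of 22 measured, 19 rose and 0 fell, the same adjusted over the list alone, with a median log2 fold change of 0.58. Without saline library 1, 12 rose and 0 fell. Rrm2, of nucleotide synthesis, rose 2.61-fold, the helicase subunits Mcm6 and Mcm4 rose 1.89- and 1.72-fold, and Mki67, a proliferation marker, rose 1.37-fold. The Mki67 call ended without saline library 1 (adjusted p 0.0861, limma) or 2 (adjusted p 0.0819, limma). Camera gave an adjusted p of 6.92e-06, and adjusted p = 0.665 with an estimated correlation.

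Genes of bone morphogenetic protein (BMP) and transforming growth factor beta signalling rose. Of 28 measured, 16 rose and 0 fell, the same adjusted over the list alone, with a median of 0.32. Fst, Nog and Chrd encode secreted antagonists and rose 2.84-, 2.61- and 1.89-fold, and Smad7, an inhibitory Smad, rose 1.68-fold. Bmp2 had a log2 fold change of 0.084 ± 0.17 (SE; adjusted p 0.705, limma). The camera adjusted p was 0.000293, with adjusted p = 0.147 with an estimated correlation.

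Matrix genes rose in part. Of 22 collagen and fibrosis genes 10 rose and 0 fell, the same adjusted over the list alone. Lox, a collagen cross-linking enzyme, rose 4.25-fold, Thbs1, a thrombospondin, 5.38-fold, Timp1, a protease inhibitor, 3.35-fold and Ccn2 3.19-fold. Col1a1, the type I collagen chain, had a log2 fold change of -0.15 ± 0.15 (SE; adjusted p 0.412, limma). Its library means, past the threshold in the exact permutation test (adjusted p 0.00699), did not pass with members scaled to unit SD (adjusted p 0.0839). By camera the list had an adjusted p of 0.00213, and adjusted p = 0.693 with an estimated correlation. The call ended with the fibre covariate (median 0.047, adjusted p = 0.293).

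Skeletal genes went both ways. Of 12 osteoblast genes 2 rose and 3 fell, the same adjusted over the list alone (camera adjusted p 0.849). Sp7, a transcription factor of bone formation, went from 2.13 ± 0.40 to -1.01 ± 0.59 log2 CPM (SD, n = 4 and 9), 8.82-fold lower. Alpl, alkaline phosphatase, was 1.66-fold lower. Runx2, which acts before Sp7 in bone cells, rose 1.63-fold and Spp1, osteopontin, 3.25-fold. Of 15 chondrocyte genes 2 rose and 2 fell, or 1 and 2 adjusted over the list alone (camera adjusted p 0.849). Prg4, lubricin, rose 6.84-fold and Col11a2, a cartilage collagen, was 2.39-fold lower. Sox9, the cartilage transcription factor, had a log2 fold change of 0.16 ± 0.11 (SE; adjusted p 0.231, limma). Saline library 3 had the highest means of both lists, at 3.38 for osteoblast and 3.12 for chondrocyte genes. The difference in library means, dexamethasone minus saline, was -0.10 for osteoblast and -0.081 for chondrocyte genes. Without that library it turned to 0.26 and 0.25 (exact permutation, adjusted p 0.0606 and 0.0718). Of 12 mineralisation genes 4 rose and 3 fell, the same adjusted over the list alone (camera adjusted p 0.413). By library mean the list went from 4.79 ± 0.19 to 5.04 ± 0.10 log2 CPM (SD, n = 4 and 9; exact permutation, adjusted p 0.0336), and fry gave an adjusted p of 0.00299. By library means the call was lost without saline library 1 (adjusted p 0.0758), 2 (adjusted p 0.0909) or 5 (adjusted p 0.109), with median centring (adjusted p 0.0642) and with members scaled to unit SD (adjusted p 0.271). With the fibre covariate it passed camera (adjusted p 0.0386). Slc20a1, a phosphate transporter, rose 2.25-fold and Enpp1, which makes the mineralisation inhibitor pyrophosphate, 2.22-fold, and Car2 was 2.15-fold lower.

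Other connective tissue lists did not pass camera. Of 18 fibro-adipogenic progenitor genes, from the mesenchymal cells of muscle, 5 rose and 6 fell, or 6 and 6 adjusted over the list alone (camera adjusted p 0.849). Cxcl14 rose 2.77-fold and Lum was 1.85-fold lower, while Pdgfra had a log2 fold change of -0.032 ± 0.094 (SE; adjusted p 0.81, limma). Of 8 tenocyte genes 4 rose and 2 fell, the same adjusted over the list alone (camera adjusted p 0.237), Scx rising 1.82-fold and Tnc 2.30-fold. Their library mean went from 5.05 ± 0.23 to 5.35 ± 0.14 log2 CPM (SD, n = 4 and 9; exact permutation, adjusted p 0.042), and fry gave an adjusted p of 0.00157. Tenocyte library means no longer passed without saline library 1 (adjusted p 0.115), 2 (adjusted p 0.0955) or 5 (adjusted p 0.136), or without any of 6 dexamethasone libraries (adjusted p from 0.051 to 0.0606). In these fits the difference was 0.25 to 0.31, against 0.31 over all 13 libraries. The call also ended with median centring (adjusted p 0.0615) and with members scaled to unit SD (adjusted p 0.0699). Of 13 osteoclast genes 3 rose and 2 fell, the same adjusted over the list alone (camera adjusted p 0.849), and 1 and 3 without saline library 1. Tnfrsf11b, a decoy receptor that restrains osteoclasts, rose 2.37-fold.

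In the main fits adipocyte genes passed camera alone, and vessel, nerve and blood lists did not pass. Of 14 adipocyte genes 10 rose and 1 fell, the same adjusted over the list alone. Lep, leptin, rose 2.69-fold, Retn 1.90-fold and Cebpa 1.42-fold, and Car3 was 1.64-fold lower. Camera gave an adjusted p of 0.0355, and adjusted p = 0.915 with an estimated correlation. The list did not pass by library means (exact permutation, adjusted p 0.0543) or by fry (adjusted p 0.0629). By library means it passed without saline library 1 (adjusted p 0.0341) or dexamethasone library 8 (adjusted p 0.0323). The camera call ended without saline library 3 (adjusted p = 0.139) or saline library 5 (adjusted p = 0.149), with the fibre covariate (adjusted p = 0.107) and with genes of mean log2 CPM of at least 1 (adjusted p = 0.0583). Of 14 endothelial genes 1 rose and 2 fell, or 0 and 2 adjusted over the list alone (camera adjusted p 0.615), Sox17 being 1.38-fold lower. Of 11 pericyte and smooth muscle genes 2 rose and 1 fell, the same adjusted over the list alone (camera adjusted p 0.849). By library means this list had an adjusted p of 0.206 (exact permutation). It passed with members of mean log2 CPM of at least 1 (adjusted p 0.0187) and without dexamethasone library 8 (adjusted p 0.0428). Of 10 nerve genes 1 rose and 2 fell, or 1 and 1 adjusted over the list alone (camera adjusted p 0.788). Of 9 erythroid and platelet genes 1 rose and 1 fell, the same adjusted over the list alone (camera adjusted p 0.788).

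Immediate early and stress genes, which also respond to tissue handling, rose. Of 14 measured, 8 rose and 0 fell, the same adjusted over the list alone. Junb rose 3.36-fold, Egr1 3.02-fold, Ier3 2.68-fold and Ier2 2.06-fold. The camera adjusted p was 0.00442, with adjusted p = 0.665 with an estimated correlation. That call ended with the mouse number as a block on the 8 libraries numbered in both groups.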

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

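The test for mislabelled or undosed mice was chosen only after the result was seen, bounds included; the minimum of 3 measured genes for the lymph node test was also set after its value was seen. The other tests and their bounds were written first.

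Of 348 comparisons of a library with its group, 36 had a library far from the rest, of which 29 were dexamethasone library 4 and 4 were saline library 3; chance gives about 1 in 20. The 7173 genes called between the groups exceeded chance: 1 of 100 splits of the libraries into 4 and 9, the real one, gave as many, and the highest other gave 1.

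Dexamethasone library 4 was highest of its group for 20 of the 22 receptor targets. Its values on the log2 CPM scale were 7.92 for Fkbp5, 7.89 for Tsc22d3, 6.43 for Arrdc2, 6.82 for the mean of receptor targets and 6.34 for that of atrophy genes. It was also highest for Ccl2 at 6.61, Ccl7 at 5.86, Prg4 at 9.02, Cxcl14 at 7.88, Pdgfra at 6.76, Pf4 at 6.01, Il1r2 at 2.71 and the reparative macrophage mean at 6.03. Eif4ebp1 at 6.94, Foxo1 at 5.84 and Sdc4 at 6.25 were highest there as well. It was lowest for Actc1 at 8.77, Myh3 at 10.1, Nr3c1 at 6.15, Pax7 at 3.37, Lif at 2.86, Tagln at 6.24, Cd74 at 6.95, H2-Ab1 at 5.78, H2-Eb1 at 5.29 and H2-Aa at 5.48. The means of myocyte fusion genes at 7.57, lymphocyte genes at -1.81 and dendritic genes at 2.71 were lowest there too.

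On the lymphocyte list 0 of 9 dexamethasone libraries reached the saline range. This was already known when the test for a mislabelled or undosed mouse was chosen. The test restates that result and cannot decide the question. A shorter time since the last dose in mouse 4, with lower hormone drive in the other 8 from their suppressed own hormone, may account for the pattern. It stays open: 12 further hormone-induced genes were 0.27 above the highest of the other 8, where over 0.5 was set before as the bound in favour. They were 0.39 above the mean of the other 8, where under 0.1 was the bound against. A different clock phase at harvest stays open as well. The groups differed by -0.251 in clock output minus Arntl arm (exact permutation p of 0.154). A size under 0.25 was the bound against it, which was just missed. Over 0.5 with a p under 0.05 was the bound in favour. That test compared groups and decides little about 1 mouse, in which the value was 0.97 against 1.38 to 1.93 in the other 8.

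Lymphocyte markers were lower in all 9 dexamethasone libraries. A loss of all low genes from depth or the log scale is argued against, since the median log2 fold change of 3316 other genes of similar level was -0.053. Lymph node tissue in the saline libraries cannot be told apart from fewer lymphocytes in the muscle. The only measured stroma gene of 5, Cxcl13, was higher by 1.04, which met the bound against lymph node tissue, but macrophages also make it and 1 gene was taken as too few. Glycam1, of lymph node vessels, was lower with the lymphocyte genes. Lower lymphocyte numbers under the drug remain a hypothesis.

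Saline library 3 stood apart for Lcn2 at 5.06, Mcemp1 at 1.08, the neutrophil mean at 3.48 and the chondrocyte mean at 3.12. Bone and marrow taken with the muscle may account for this, and 5 marrow precursor genes were 1.98 above the highest other saline library, just short of the bound of 2 set before, so it stays open. These values do not tell bone taken with the muscle apart from bone formed in it, for which the submitters excluded another saline mouse. More blood in the sample also stays open, since 5 further cartilage and bone genes were 0.72 above the highest other saline library and 0.85 above the mean of the other 3. The bounds were over 1 for the first, against blood, and under 0.5 for the second, in its favour.

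Other libraries far from their group were saline library 1 for Per1 at 6.83, saline library 2 for Pdgfra at 6.63, and dexamethasone library 1 for Il6st at 8.27.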

How the results depend on the processing

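The alternatives named as added after seeing the data are leaving out saline library 3 and dexamethasone library 4 together, the 8 numbered libraries without a block, and voom for lists and single genes. The count of 7173 genes ranged from 6306 to 7173 when 1 library was left out, and was 6422 without both doubted libraries. It fell to 3381 with the fibre covariate, 2882 of them shared. The fibre list mean itself separated the groups, at 12.18 in the lowest saline and 12.15 in the highest dexamethasone library. The covariate thus overlaps with group, so this drop and the calls ended by this covariate cannot be put down to fibre content. The cause was not tested. The count of 774 genes changed at least 2-fold was 739 to 805 when 1 library was left out, 318 with log2 of CPM plus 1, which shrinks low genes, and 376 with a minimum mean log2 CPM of 1, which tests fewer genes; in both, rises outnumbered falls. The 13 lists past camera became 0 with an estimated correlation, which was up to 0.847, 10 with genes of mean log2 CPM of at least 1, where the T, B and NK cell list kept too few members to be tested, and 12 to 14 when 1 library was left out. The 16 lists differing by library means were 13 to 17 when 1 library was left out, and 11 with members scaled to unit SD. Mouse numbers 1, 2, 3 and 5 occur in both groups. Same-numbered libraries had correlations of -0.024, -0.094, -0.049 and 0.20, and 0 of 4 matched best with its own number. These values show no sign of pairing, but 4 numbers are too few to exclude it. With the number as a replicate block on those 8 libraries, 5959 genes were called, against 6124 without the block, and 791 changed at least 2-fold. Under this block 12 lists passed camera, without the immediate early list (adjusted p 0.122). Per1 stood at -0.30 on these 8 libraries with the block (adjusted p 0.0213, limma), against 0.011 over all 13 libraries. Each number occurs in both groups, so the block cannot move this difference, which comes from the libraries kept. Under sign flips of 4 pairs 0 lists differed, since the smallest p is 0.125. With the fibre covariate the mature fibre list went to a median of 0.063 by construction. Of 3868 values of the 147 genes picked by the naming rule under alternatives, 3729 stayed on the same side of the threshold. Of the rest 101 lost the call, 37 gained it and 1 reversed direction. Depth limited low genes such as Serpina3m, with 1 to 3 reads in saline.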

Other observations

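The lists in this part were chosen after their values were seen, so their counts, medians and p-values are not independent evidence.

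Imprinted genes, expressed from 1 parental copy and many of them active in growth, were lower under dexamethasone. Of 21 measured, 14 fell and 2 rose, and the mean went from 6.26 ± 0.12 to 5.63 ± 0.08 log2 CPM (SD, n = 4 and 9; exact permutation p of 0.0028, the smallest possible). Peg10 fell by 1.66 ± 0.07 on the log2 scale (SE), Cdkn1c, a cell cycle inhibitor, fell by 1.58 ± 0.15, and the noncoding RNA H19 fell by 1.40 ± 0.12. Igf2, the growth factor encoded beside H19, fell by 1.16 ± 0.10 and Dlk1 fell by 1.29 ± 0.20.

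Acute phase genes rose as a group: 15 of 15 measured were higher, with a median log2 fold change of 1.95. Lrg1 rose by 1.95 ± 0.14 on the log2 scale (SE), Orm1 by 1.34 ± 0.21 and Steap4, a metalloreductase, by 0.95 ± 0.10. The mean went from 3.44 ± 0.12 to 5.81 ± 0.28 log2 CPM (SD, n = 4 and 9).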
